A study of Mus musculus with 4 samples.

How the data were processed

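FXR ChIP-seq was done on livers of mice given the FXR agonist GW4064, in 2 ChIP libraries with 2 input libraries. The labels give the treatment of the inputs as none. Their titles and the labels' protocols pair them with the ChIP libraries, so they were taken as inputs of the same livers. If they came from untreated livers, each fold would also carry differences between livers. Per the labels' protocols, chromatin was crosslinked with formaldehyde and sonicated, a small part was kept as input, the rest was immunoprecipitated with an FXR antibody, and libraries were sequenced as read pairs on an Illumina NovaSeq after PCR. Grouping followed the library titles. The submitters' processing notes name fastp 0.20.1, Bowtie2 2.4.2, MACS2 2.2.7.1, ChIPseeker and HOMER 4.11.1 and the build GRCm38.p6. Settings, duplicate handling and read totals are not given in the sources used here. Nothing in the labels says that the 2 ChIP libraries come from separate animals, so p-values measure only these samples and their peaks.

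The deposited data used were 1 annotated peak table per ChIP library, not pooled, and per the peak names in the tables each ChIP was called against the input of the same number. The fold enrichment of a peak is the authors' ratio of ChIP over input at that peak. The authors' significance values are deposited as −log10 p and −log10 q, and both tables stop at p = 0.05. Peak width, the signed distance to the nearest TSS, the annotation class and the nearest gene are also the authors' deposited values. All promoter classes matched that distance (3 kb or less) in both tables. Peak tables give no summit, so midpoints stood in for it, and the inputs have no values of their own in these data.

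The fragments behind each peak were recovered by solving for a whole number of ChIP fragments and an input background that together give the deposited fold, taken as (fragments + 1) over (background + 1), and the deposited Poisson p, within a relative tolerance of 0.001. This was possible for 100% of peaks of both libraries, and 100% of 4400 simulated peaks were recovered exactly. Counting intervals of a fold are 95% exact Poisson intervals on its fragments with the background held fixed. PCR copies are not independent molecules, so intervals cover counting error only. The added 1 pulls folds over a low background toward 1. Most deposited peaks rest on few fragments, so single weak peaks are imprecise, while stringent peaks had a median of 12 and 16 fragments.

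Peaks of both libraries overlapping by at least 1 bp were merged into regions with bedtools 2.31.1, and a region holding a peak of both was called shared. The number of shared regions was set against 100 random placements of the replicate 2 peaks on the same chromosomes (bedtools shuffle, one-sided permutation p), and against peaks displaced by 10 kb to both sides, which was added after the data were seen. Stringent peaks have −log10 q of at least 5. Enrichment was compared across shared regions by Spearman's rho. Promoter shares were set against random placements, and shared against single-library regions by a two-sided Fisher's exact test. For the random placements, a region counted when its edge lay within 3 kb of a TSS named in the peak lists.

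A gene's promoter peak was the strongest peak within 3 kb of a TSS that the authors assigned to it. That TSS could belong to any annotated transcript of the gene, also one starting inside it. Whether the libraries' peaks overlapped at a named gene was judged from these strongest promoter peaks only. The background was 21883 protein-coding genes of the mouse reference annotation, of which 19327 (88.3%) are named in the tables, 74 of them matched through a synonym. The 13 gene lists were known FXR targets, bile acid synthesis and conjugation, bile acid and bile lipid transport, lipoprotein, cholesterol and fatty acid metabolism, glucose metabolism, xenobiotic and bile acid detoxification, liver transcription factors and nuclear receptors, plasma proteins with complement and coagulation, autophagy and lysosome, FGF and bile acid feedback signalling, Kupffer cell and leukocyte markers, stellate, endothelial and cholangiocyte markers, and genes of neurons, muscle, eye and testis. Presence of a promoter peak in both libraries was tested by two-sided Fisher's exact tests. Strength was tested by a two-sided permutation test with 100000 random lists of the mean percentile of the fold averaged over both libraries, with 0 for a gene without a peak. Values were adjusted by Benjamini-Hochberg over the 13 lists of each family.

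Genes were named by a rule. It takes all known FXR targets, by whether they have a promoter peak in both libraries or 1, with values for the 12 highest by the lower of their 2 folds, and the 10 strongest shared promoter regions and 5 strongest distal ones on chromosomes 1 to 19 and X. It also takes 2 to 4 highest members of each other list, and always Nr0b2, Abcb11, Cyp7a1, Cyp8b1, Slc51b and Nr1h4. Members with stringent peaks are named besides, since their number is given. A few single genes that the rule or the tests reached are not reported here. The values of weaker known targets given besides were chosen after they were seen. The design, the tests, the gene lists, this rule and most alternatives were set before the data were examined.

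The steps were tested on simulated data. Of 1000 shared positions planted among 4442 peaks, 990 were found above the random mean. Of random lists drawn from 21883 genes, 3.5% passed the unadjusted presence test and 3% the strength test, and of lists with a planted effect 71.5% and 89% passed. Random lists of long genes passed the strength test in 80.5% of draws, and in 6% once random lists were matched on gene length and transcript number (planted lists, 63.5%), so matched values are given where they end a call.

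The alternatives covered the overlap that counts as shared, stricter thresholds, lists of equal length, the chromosomes kept, the promoter window, the gene assignment, the background and each library alone. A search for the FXR motif (an inverted repeat of the nuclear receptor recognition element) was planned and not run, since no genome sequence was used here. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.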

Results

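Chromatin bound by FXR (gene Nr1h4), the nuclear receptor for bile acids, was profiled by chromatin immunoprecipitation and paired-end sequencing in livers of mice given GW4064, a synthetic FXR agonist. The series held 4 libraries, of which 2 were FXR ChIP libraries and 2 were inputs (sonicated chromatin sequenced without antibody). Each ChIP library had a deposited peak list called against the input of the same number, so the inputs enter only through those calls. The labels give the treatment of the inputs as none, while the labels' protocols take input and ChIP from the same sonicated chromatin. No ChIP library came from mice without the agonist or from a control antibody, and no comparison between conditions was possible. Replicate 1 held 879314 peaks covering 184 Mb, and replicate 2 held 492227 peaks covering 125 Mb. Total read numbers are not given in the sources used here. As a measure of depth, the median peak rested on 3 fragments in replicate 1 and on 4 in replicate 2. Peaks of 4 fragments or fewer made up 82.6% of the first list and 57.4% of the second. Both lists stop at an unadjusted p of 0.05 per peak, and 9.92% and 8.14% of their peaks had q of 0.05 or less. A stringent subset with −log10 q of at least 5 held 4442 peaks in replicate 1, with a median of 12 fragments, and 2908 in replicate 2, with a median of 16. Fold enrichments below are the authors' own values per peak and serve to describe, rank and filter peaks, so both libraries' values are given rather than a mean. All coordinates are on GRCm38.p6.

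To find which FXR sites recurred, the peak lists of the 2 libraries were overlapped. The strongest promoter site in both lists lay at Mkln1, which encodes the intracellular protein muskelin (chromosome 6, 31396155 to 31399141), with a fold enrichment of 50 in replicate 1 and 99.2 in replicate 2. It was followed by Arhgef7, a guanine nucleotide exchange factor (chromosome 8, 11753216 to 11756937), at 41.2 and 67.2, and by Rwdd3 (chromosome 3, 121169852 to 121176244) at 36.6 and 42.4. Ptgds, which makes prostaglandin D2, had folds of 33.4 and 42.3 (chromosome 2, 25471620 to 25473999). At Cth, whose product makes cysteine from cystathionine, the region on chromosome 3 from 157924768 to 157927828 had folds of 30 and 45.2; the replicate 1 peak was assigned by the authors to the neighbouring gene 1810013D15Rik. Ttc3, Sfxn2, Syne1, Usp18 and Gm49350 completed the 10 highest promoter regions, with lower-of-2 folds from 32.4 down to 23.2.

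Sites far from a transcription start site (TSS) were as strong. The 5 highest lay nearest to Apol7c, Gm16202, Gm50155, Pank3 and Gm50067. The region 6.38 kb from Apol7c, an apolipoprotein L family gene, was intergenic (chromosome 15, 77539669 to 77540581) and had folds of 62.6 and 38.9, on 131 and 110 fragments. The region 36.2 kb from Pank3, a pantothenate kinase of coenzyme A synthesis, was also intergenic (chromosome 11, 35732262 to 35733246). Its folds were 37.4 and 125.63. The region 37.9 kb from Gm16202 (chromosome 9, 86354399 to 86357608) lay in an intron of another gene and had folds of 37.9 and 75.6. Those 11.5 kb from Gm50155 and 181 kb from Gm50067 had folds of 37.9 and 64.8, and of 47.1 and 34.5.

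Over all deposited peaks, 155851 of 1195963 merged regions held a peak of both libraries with at least 1 bp of overlap. Random placement of the replicate 2 peaks gave 68409 ± 254 such regions (SD over 100 placements), so the observed number was 2.28 times the random mean (one-sided permutation p = 0.0099, the smallest that 100 placements can give). Among stringent peaks, 1779 regions were shared against 11.6 ± 3.52 at random, a 153-fold excess with the same p. Displacing the peaks of 1 library by only 10 kb left 132.5 shared stringent regions, which keeps the local density of peaks, and the excess over that was 13.4-fold. For all peaks the same displacement left 94098.5 shared regions, and the excess was 1.66-fold.

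The share of peaks found in the other library rose with the fragments behind them up to 12 to 23 fragments. In replicate 1 it was 14.6% for peaks of 2 to 3 fragments (10.0% after displacement) and 96.0% for peaks of 12 to 23 fragments (33.9% after displacement). In replicate 2 the same classes had 24.4% (16.8%) and 98.1% (46.8%). Peaks of 24 or more fragments were found slightly less often, in 92.0% (36.2%) and 97.3% (52.4%). Of the 1000 strongest peaks by fold, 99.6% of those in replicate 1 and 99.9% of those in replicate 2 were in the other list. The plain overlap of all deposited peaks therefore lay much nearer to random placement than the overlap of stringent peaks did.

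**Figure D1:**
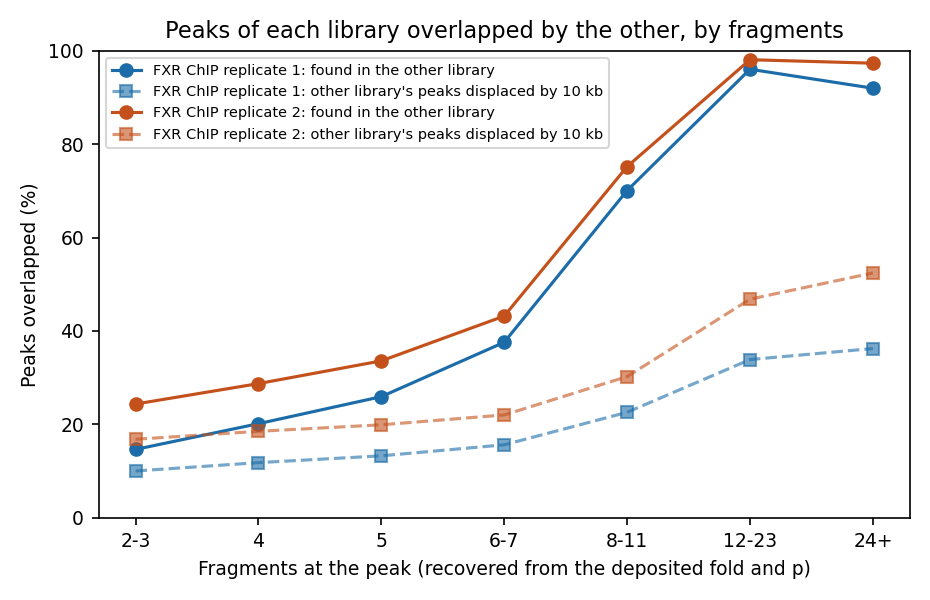
Percent of each FXR ChIP library's peaks overlapped by a peak of the other library (circles) and after displacing the other library's peaks by 10 kb (squares), by the number of fragments at the peak. At 12 to 23 fragments 96.0% of replicate 1 and 98.1% of replicate 2 peaks were overlapped, against 33.9% and 46.8% after displacement.

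To see how alike the 2 libraries ranked the shared sites, their fold enrichments were compared. At some genes of bile acid transport and feedback the 2 folds were close. Abcb4, a phospholipid exporter of bile, had 25.1 and 23, and Mafg, a transcriptional repressor, had 22.5 and 25.3. Other genes differed more in their 2 values. Slc51b, a subunit of the basolateral bile acid exporter, had 18.0 and 40.9, and Pcx, the pyruvate carboxylase of gluconeogenesis, had 10.0 and 23.8. Across the 155851 shared regions, Spearman's rho of the libraries' fold enrichments was 0.207. It was 0.489 across the 1781 shared regions whose strongest peak was stringent in both libraries. Of the 1000 strongest peaks of replicate 1 by fold, 54.8% overlapped the 1000 strongest of replicate 2. Regions are not independent replicates, so no p is attached to these coefficients.

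**Figure D2:**
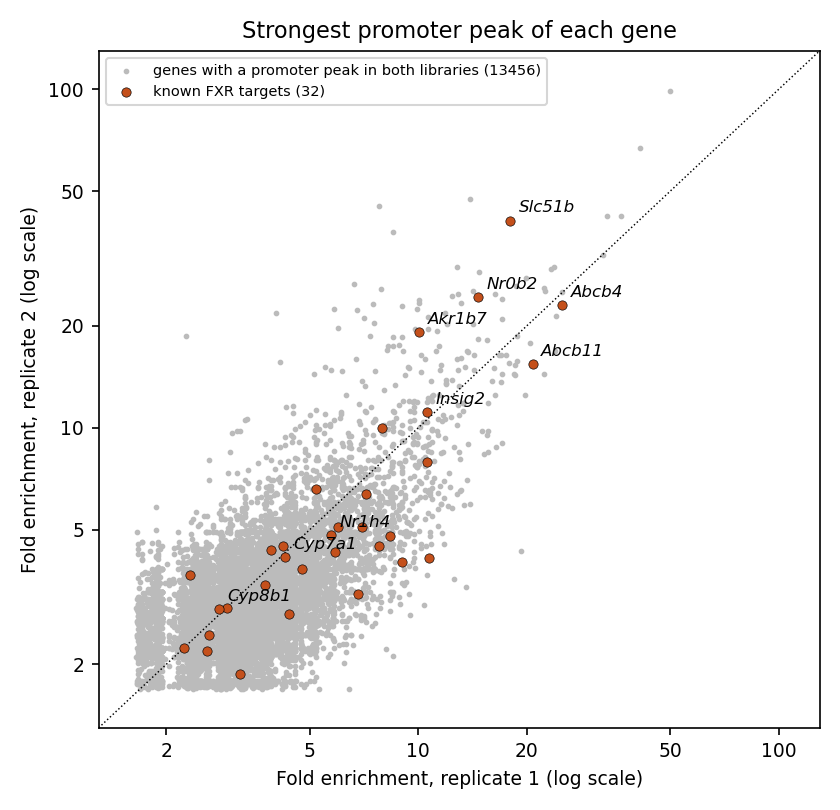
Fold enrichment of the strongest promoter peak (within 3 kb of a TSS) of each protein-coding gene in FXR ChIP replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), for the 13456 genes with such a peak in both libraries, overlapping or not. The dotted line marks equal values. Known FXR targets are in orange, with Abcb4 at 25.1 and 23 and Cyp8b1 at 2.80 and 2.91.

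The position of FXR sites relative to promoters was compared between shared regions, regions of 1 library and random placements. Of the 1781 stringent shared regions, 41.4% were in the authors' promoter class (within 3 kb of a TSS), against 17.6% ± 1.08 in random placements. Those within 1 kb of a TSS made up 28.4%, introns 25.9% and distal intergenic regions 25%. Shared regions of all deposited peaks were in promoters in 18.2% of cases (14.6% ± 0.0843 at random), and 45.5% of them were distal intergenic. Regions of 1 library were in promoters in 14.7% (14.0% ± 0.0303 at random). Scored by region edges within 3 kb of a TSS, as the random placements were, the 3 shares were 42.3%, 18.5% and 14.7%. Each exceeded all 100 random placements (one-sided permutation p = 0.0099, the smallest they can give). Only TSSs named in the peak lists were counted, and placements were not kept off unmappable sequence. Both can lower the random share, so the small excess in regions of 1 library is not read as a promoter preference. Shared regions were in promoters more often than regions of 1 library (odds ratio 1.29, two-sided Fisher's exact p = 5.93e-276). This p counts regions, which are neither samples nor independent of each other.

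Genes known to be FXR targets were examined first. Of the 34 known targets listed, 32 had a promoter peak in both libraries and 10 had a stringent one in both: Abcb11, Abcb4, Akr1b7, Fgb, Insig2, Nr0b2, Osgin1, Rdh9, Scarb1 and Slc51b. At Abcb11 (ENSMUSG00000027048), the canalicular bile salt export pump, peaks spanned a TSS in replicate 1 (chromosome 2, 69341448 to 69344338) and in replicate 2 (69341395 to 69343786). Their folds were 20.8 on 31 fragments (95% exact Poisson interval 14.4 to 29.3) and 15.4 on 43 fragments (11.2 to 20.6). Nr0b2 (ENSMUSG00000037583), which encodes the repressor SHP, had peaks over its TSS from 133552123 to 133553930 and from 133552080 to 133559882 on chromosome 4. Their folds were 14.7 (10.1 to 20.8) and 24.4 (19 to 30.7). The wide replicate 2 peak ran past the end of the gene. It also overlapped a replicate 1 peak with a fold of 16.6, which the authors assigned to Gm23158. Slc51b had peaks over its TSS on chromosome 9, from 65422007 to 65424069 and from 65421919 to 65424051, with intervals of 13.3 to 23.8 and 33.6 to 49.4 around its folds. Abcb4 carried its peaks over an annotated TSS inside the gene (chromosome 5, 8928593 to 8930591 and 8927995 to 8929902). Some promoter peaks given below likewise lay near a TSS well inside the gene, among them those of Scarb1, Slc2a2, Ppara and Atg16l1. Whether such TSSs are used in liver was not tested. The intervals of the folds cover counting error only, with the input background taken as known.

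The next targets by the lower of their 2 folds were Insig2, a regulator of sterol sensing, at 10.6 and 11.1, and Akr1b7, an aldose reductase-like enzyme, at 10.1 and 19.2. Fgb, the fibrinogen beta chain, had 10.6 and 7.94. Osgin1 had 7.94 and 9.98, Scarb1, the HDL receptor, had 7.16 and 6.39, and Fetub had 5.21 and 6.58. Apoe, a lipoprotein component, had 6.98 and 5.11, and Slc27a5, a bile acid-CoA ligase, had 5.98 and 5.09. In 8 of the 12 highest targets the strongest promoter peaks of the 2 libraries overlapped. The exceptions were Osgin1, Fetub, Apoe and Slc27a5. Here and for the genes below only the strongest promoter peak per library was compared. A peak counted as not overlapping can therefore still overlap a weaker peak of the other library. Folds of at least 5 in both libraries were found only at these 12 of the 34 known targets. Besides Nr1h4, Cyp7a1 and Cyp8b1, described below, the others with a promoter peak in both libraries were Abcc2, Pltp, Nr1i3, Abcg5, Rdh9, Baat, Sdc1, Apoc2, Slc10a1, Cd36, Vldlr, Apoc3, Abcg8, Fgfr4, Slc51a, Kng1 and Abcc4. Among the weakest of them were Slc51a, the other subunit of the basolateral bile acid exporter, at 2.24 and 2.24, Kng1 at 2.60 and 2.19, and Abcg8 at 2.63 and 2.45.

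The promoter peaks of Cyp7a1 and Cyp8b1, bile acid synthesis genes that FXR signalling is known to repress, rested on few fragments. At Cyp7a1 (ENSMUSG00000028240), the rate-limiting enzyme of bile acid synthesis, the fold was 4.27 on 6 fragments (1.95 to 8.58) in replicate 1, 561 bp upstream of a TSS on chromosome 4 (6276194 to 6276371). In replicate 2 it was 4.15 on 8 fragments (2.05 to 7.72), 2292 bp upstream (6277925 to 6279153), and the 2 peaks did not overlap. The strongest peaks assigned to Cyp7a1 at any distance were intergenic, 15.6 and 7.67 kb from a TSS. Their folds were 4.50 and 4.93, and they did not overlap either. Cyp8b1, the sterol 12-alpha-hydroxylase, had promoter folds of 2.80 (1.17 to 6.30) and 2.91 (1.33 to 5.85), at −log10 q of 0.713 and 0.735, from peaks that did not overlap. Its strongest assigned peaks lay farther out in intergenic sequence, 4.82 and 4.10 kb from a TSS on chromosome 9 (121921121 to 121921688 and 121920407 to 121921742), with folds of 5.74 and 4.61. These 2 peaks overlapped, on 9 fragments in each library. Nr1h4 itself had overlapping peaks (chromosome 10, 89531710 to 89532622 and 89532021 to 89532995) with folds of 5.73 and 4.82. Sult2a1, a bile acid sulfotransferase, had a promoter peak only in the replicate 1 list (fold 2.60), and Fgf21, a hepatic hormone, only in the replicate 2 list (2.07).

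Whether FXR peaks concentrated at groups of genes was tested for 13 lists, with 3 families of 13 tests each: presence of a promoter peak in both libraries, presence of a stringent one, and strength. Promoter peaks in both libraries were found at 13456 of 21883 protein-coding genes (61.5%), and stringent ones at 500 (2.28%). The 2 peaks of a gene did not need to overlap. The known FXR targets exceeded other genes in presence (94.1% against 61.4%, two-sided Fisher's exact p = 2.33e-05, adjusted p = 7.57e-05) and in stringent presence (29.4%, 95% exact interval 15.1 to 47.5%, against 2.24%; raw exact p = 2.84e-09, adjusted p = 1.23e-08). Of these 34 genes, 31 are also in another list, so the lists are not independent of each other. Strength was the mean percentile, among all protein-coding genes, of the strongest promoter peak's fold averaged over both libraries. The mean percentile of the known FXR targets was 82.3 against 50 for random lists (two-sided permutation p = 1e-05, the smallest that 100000 random lists can give; adjusted p = 1.62e-05). That smallest p was also reached by 7 other lists. Random lists matched on gene length and transcript number, added after the data were seen, had a mean percentile of 56.9 for the known FXR targets (adjusted permutation p = 2.6e-05). The presence tests were not matched on either.

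Genes of bile acid and bile lipid transport had promoter peaks in both libraries at all 18 members (adjusted Fisher's exact p = 0.00062, raw 0.000286). Stringent peaks were found at 7 of them: Abcb11, Abcb1a, Abcb4, Atp8b1, Slc51b, Slco1a4 and Slco1b2 (38.9%, 17.3 to 64.3%; raw exact p = 7.98e-08, adjusted p = 2.07e-07). Abcb1a, a multidrug exporter, had folds of 9.46 and 12. The mean percentile was 86.5 (permutation p = 1e-05). In the list of bile acid synthesis and conjugation, 20 of 23 genes had a promoter peak in both libraries (raw exact p = 0.0101, adjusted p = 0.0164) and 4 had a stringent one (raw exact p = 0.00169, adjusted p = 0.00366). These were Akr1d1, a steroid 5-beta-reductase, at 8.63 and 13.4, Slc27a2, a fatty acyl-CoA synthetase, at 10.5 and 6.57, Amacr, a peroxisomal racemase, at 6.43 and 9.43, and Cyp27a1, the sterol 27-hydroxylase, at 6.26 and 6.66. Their strongest promoter peaks overlapped between libraries only at Akr1d1. The mean percentile of this list was 77.9 (permutation p = 1e-05), and its presence had an adjusted exact p of 0.146 with replicate 1 alone and of 0.0954 against only genes named in the peak lists.

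Lipoprotein, cholesterol and fatty acid genes had promoter peaks in both libraries at 43 of 45 members (raw exact p = 2.18e-07, adjusted p = 2.84e-06). The 10 with stringent peaks (raw exact p = 5.52e-08, adjusted p = 1.79e-07) included Apoa5, Cpt1a, Insig2, Lcat, Lipc, Lrp1, Plin2 and Scarb1. Plin2, a lipid droplet protein, had folds of 16.9 and 13.7 at its promoter on chromosome 4 (86669871 to 86672247 and 86669768 to 86672541). Lrp1, a lipoprotein receptor, had 8.27 and 7.23. The mean percentile was 83.8 (permutation p = 1e-05). Of 19 genes of glucose metabolism, 16 had a promoter peak in both libraries (raw exact p = 0.0566, adjusted p = 0.0669), which did not pass. Stringent peaks, at Creb3l3, Pcx and Slc2a2, did pass (3 of 19, raw exact p = 0.00875, adjusted p = 0.0162), as did strength (mean percentile 76.6, permutation p = 2e-05, adjusted p = 2.89e-05). Slc2a2, the hepatic glucose transporter, had 10.9 and 9.11, Creb3l3, a liver-enriched transcription factor, had 10.7 and 6.55, and Pygl, the liver glycogen phosphorylase, had 7.62 and 5.42. The strongest promoter peaks of the libraries did not overlap at Creb3l3 and Pygl.

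Genes of xenobiotic and bile acid detoxification had the highest mean percentile of the 13 lists, 89.7 (permutation p = 1e-05). Promoter peaks in both libraries were found at 25 of 27 (raw exact p = 0.000495, adjusted p = 0.000919), and stringent ones at 11 (40.7%, 22.4 to 61.2%; raw exact p = 7.45e-12, adjusted p = 9.68e-11). The 11 were Akr1b7, Ces1d, Ces2a, Cyp2c29, Cyp3a11, Cyp3a13, Cyp4a14, Gsta2, Gsta4, Sult2a8 and Ugt1a1. Gsta4, a glutathione transferase, had folds of 10.6 and 11.9, Cyp3a13, a cytochrome P450, had 10.3 and 10.4, and Sult2a8, a bile acid sulfotransferase, had 9.65 and 8.94. At Sult2a8 the strongest promoter peaks of the libraries did not overlap. Counting peaks at any distance from the gene, the presence test of this list and that of the bile acid synthesis list no longer passed (adjusted exact p = 0.16 and 0.282).

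Plasma protein, complement and coagulation genes, which hepatocytes secrete in bulk, had promoter peaks in both libraries at 38 of 41 (raw exact p = 1.33e-05, adjusted p = 5.78e-05). Stringent peaks were found at 12 (29.3%, 16.1 to 45.5%; raw exact p = 7.69e-11, adjusted p = 5e-10): Alb, Ambp, C3, Cfb, Fgb, Fgg, Hc, Hp, Pros1, Rbp4, Serpina3k and Serpinc1. Hc, complement C5, had folds of 16.3 and 15.1, and C3, the central complement component, had 12 and 13.8. Rbp4, the retinol carrier, had 9.95 and 11.9, and Serpinc1, antithrombin, had 9.48 and 9.98. The peaks of the libraries overlapped at all 4 of these genes, and the mean percentile of the list was 83.7 (permutation p = 1e-05).

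Liver transcription factors and nuclear receptors had promoter peaks in both libraries at 36 of 37 (raw exact p = 5.08e-07, adjusted p = 3.3e-06), the exception being Foxa3, and the mean percentile was 82.1 (permutation p = 1e-05). Stringent peaks were found at Nr0b2, Nr1i2 and Ppara only, which did not pass (raw exact p = 0.052, adjusted p = 0.0751). At a fold of at least 5 in both libraries 6 of 37 had a promoter peak (adjusted exact p = 0.00275), and at q of 0.05 or less 22 did (4.12e-10). Ppara, the receptor that drives fatty acid oxidation, had folds of 9.74 and 9.11. Nr1d2, a clock repressor, had 6.04 and 5.93, from peaks that did not overlap. Nr1i2, the xenobiotic receptor PXR, had 6.64 and 26.6 in its promoter window, from peaks that did not overlap. The replicate 2 peak there overlapped an intronic peak of replicate 1 with a fold of 27.1, 3.70 kb from a TSS (shared region on chromosome 16, 38284885 to 38292108). In the list of FGF and bile acid feedback signalling, 12 of 15 genes had a promoter peak in both libraries (raw exact p = 0.187, adjusted p = 0.202) and Mafg and Nr0b2 had stringent ones (raw exact p = 0.045, adjusted p = 0.073), so neither test passed. Presence did pass at a fold of at least 5 (5 of 15, adjusted exact p = 0.00022), at q of 0.05 or less (6 of 15, 0.0154) and within 1 kb (80% against 42.5%, 0.00948). The Mafg peaks lay on chromosome 11 (120630244 to 120632562 and 120629698 to 120632690). Klb, the FGF co-receptor beta-klotho, had 5.83 and 5.27, and Nr5a2, the receptor LRH-1, had 8.20 and 5.22. The strongest promoter peaks of the libraries did not overlap at Klb and Nr5a2. The strength test passed for this list (mean percentile 69.1, permutation p = 0.00878, adjusted p = 0.0104) and did not against random lists matched on gene length and transcript number, which were added after the data were seen (adjusted permutation p = 0.0961). That match counts only transcripts named in the peak lists, so the lost call does not show that length or transcript number was the source.

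Autophagy and lysosome genes, a group that nuclear receptors are known to regulate in liver, had promoter peaks in both libraries at 30 of 32 (raw exact p = 6.7e-05, adjusted p = 0.000174), yet none was stringent in both (0 of 32, upper exact bound 10.9%; exact p = 1). Atg16l1, Gabarapl1, Uvrag and Atg7, which act in autophagosome formation, had the highest promoter folds, at 6.96 and 5.10, 5.47 and 4.98, 6.22 and 4.73, and 6.82 and 4.38. The peaks of the libraries overlapped at these genes except Atg7. Outside the 3 kb window, a shared region assigned to Sqstm1, also in this list, had folds of 33.5 and 52.3. It lay 4.245 kb from a TSS and was picked after its values were seen. The mean percentile was 73.2 (permutation p = 1e-05), and against lists matched on gene length and transcript number the adjusted permutation p was 0.00565. At a fold of at least 5 in both libraries, 1 of 32 had a promoter peak (3.13% against 3.51%, adjusted exact p = 1), while at q of 0.05 or less 13 of 32 had one (40.6% against 13.9%, adjusted exact p = 0.000275).

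Among markers of other cells, those of Kupffer cells and leukocytes ranked lowest, with a mean percentile of 31.5 (permutation p = 0.00604, adjusted p = 0.00785, below the 50 of random lists). A promoter peak in both libraries was found at 7 of 18 of them (38.9% against 61.5%, raw exact p = 0.0551, adjusted p = 0.0669). Counting peaks at any distance turned that direction (83.3% against 78.3%, adjusted exact p = 0.844). Their highest folds were 3.06 and 3.61 at Cd5l, a macrophage-secreted protein, 2.57 and 2.15 at Ms4a1, which encodes CD20 of B cells, 2.15 and 2.53 at C1qc, and 3.66 and 2.11 at Ptprc, the pan-leukocyte marker CD45. The strongest promoter peaks of the libraries overlapped at none of these genes. Stellate, endothelial and cholangiocyte markers were not detectably different from other genes, with 14 of 20 carrying a promoter peak in both libraries (raw and adjusted exact p = 0.498) and a mean percentile of 54.8 (permutation p = 0.455). Pdgfrb, a stellate cell receptor, had 3.98 and 8.76, Stab2, an endothelial scavenger receptor, had 3.74 and 3.44, and Col3a1 and Reln had 4.52 and 3.34, and 3.26 and 3.28. Of these genes, only Pdgfrb had overlapping strongest promoter peaks in the libraries. Genes of neurons, muscle, eye and testis, which liver does not normally express, had promoter peaks in both libraries at 13 of 32 (40.6% against 61.5%, raw exact p = 0.018, adjusted p = 0.026) and a mean percentile of 37.6 (permutation p = 0.0141, adjusted p = 0.0153). Their highest folds were 3.86 and 4.30 at Syt1, 3.79 and 5.34 at Myh4, 5.21 and 3.63 at Gnat1 and 3.32 and 4.19 at Mylpf. The peaks of the libraries overlapped at Myh4 and Mylpf and not at Syt1 and Gnat1. None of these 3 lists had a gene with a stringent promoter peak in both libraries (0 of 18, 0 of 20 and 0 of 32; upper exact bounds 18.5%, 16.8% and 10.9%; exact p = 1 for each). The lower presence of neuron, muscle, eye and testis genes did not pass with replicate 1 alone (adjusted exact p = 0.146), replicate 2 alone (0.0551), only genes named in the peak lists (0.0748) or q of 0.05 or less (0.613). Their lower strength did not pass with replicate 2 alone (adjusted permutation p = 0.112) or against lists matched on gene length and transcript number (0.455). That match counts only transcripts named in the peak lists, so it can remove part of a true difference.

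**Figure D3:**
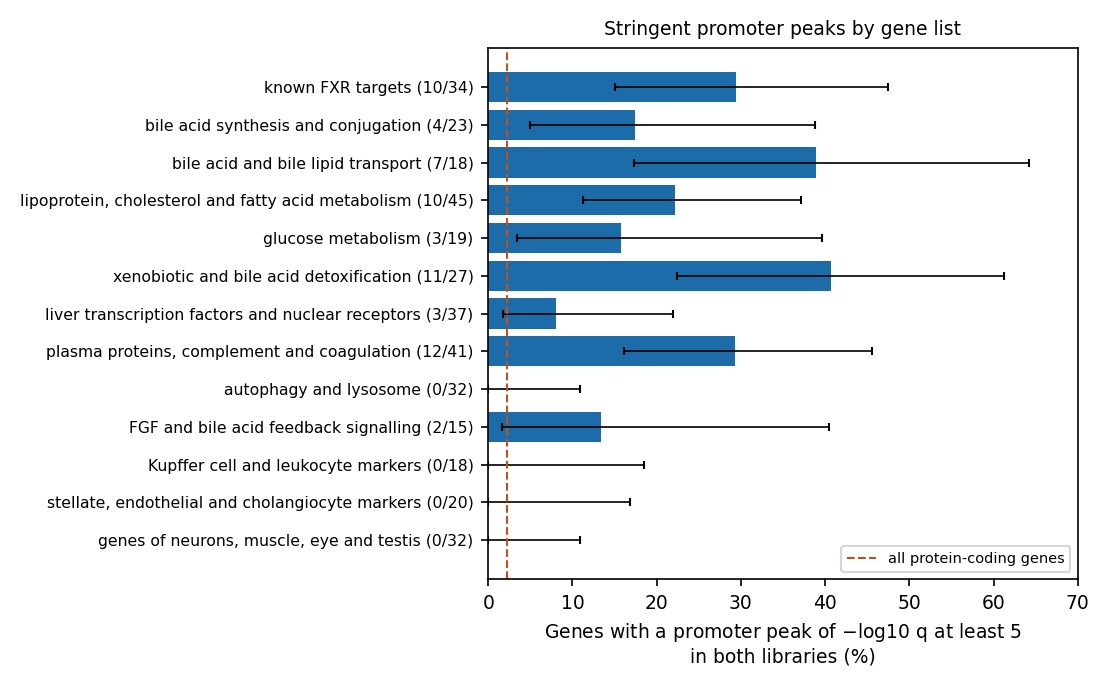
Percent of each list's genes with a promoter peak of −log10 q at least 5 in both FXR ChIP libraries (bars, with 95% exact binomial intervals), with the number of such genes over the number listed; the dashed line marks all protein-coding genes (2.28%). Detoxification and transport genes had 40.7% and 38.9%, and 4 lists had none.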

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

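No test was run on the peaks in this part, which were looked at because none of the regions or genes named above comes from the mitochondrial genome or chromosome Y. The mitochondrial genome held 9 peaks in replicate 1 and 7 in replicate 2, all stringent, in 7 shared regions. Their recovered input backgrounds ran from 56.5 to 231 fragments in replicate 1 and from 167 to 685 in replicate 2. The highest fold was 19.1 in replicate 1 and 10.2 in replicate 2 (positions 15970 to 16299 and 15940 to 16298). The authors assigned both peaks to mt-Tp, a transfer RNA gene, as the nearest gene.

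Chromosome Y held 275 peaks in replicate 1 and 74 in replicate 2, with 27 shared regions and 8 and 6 stringent peaks. The highest fold in replicate 1 was 45.9 near Gm28389 (11857765 to 11858512), and that in replicate 2 was 10.7 near Gm29277 (145315 to 145999). The labels used here do not give the sex of the mice.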

How the results depend on the processing

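Alternatives with q of 0.05 or less, without peaks of high input background, with other gene backgrounds or assignments, and with lists matched on gene length were chosen only after the data were seen. Shared regions numbered 155851 as reported, 55803 with an overlap of at least 50% of both peaks, 78130 with midpoints within 100 bp, 10387 at q of 0.05 or less, 2515 at a fold of at least 5 and 1779 at −log10 q of at least 5. Stricter rules keep fewer peaks by construction. With equal list lengths (104558), on chromosomes 1 to 19 and X (155817) or without peaks over more than 5 background fragments (155763), the number moved by less than 1.5 times. The correlation of 0.207 became 0.38 as Pearson's r of log2 folds, 0.216 for −log10 q, 0.315 with 50% overlap and 0.489 for stringent regions, and the cause was not tested. The promoter share exceeded random placements under each alternative run (8.79 to 41.6%) and in shared regions with a fold of at least 10 in both libraries (41.8%), and lay between 15.3 and 16.3% for 1 library alone. Random placements gave 14.1 and 14.2% for 1 library alone, so that excess was small and has the limits of the placements given above.

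Of the 13 lists, 9 differed from other genes in presence, and 7 to 11 did under the alternatives, 7 to 8 with 1 library alone. The autophagy and lysosome list changed direction, from more to less often than other genes: its difference was -2.29 percentage points at −log10 q of at least 5 and -0.39 at a fold of at least 5, neither past the threshold and on 0 and 1 of 32 genes, while at q of 0.05 or less it stayed higher (13 of 32, adjusted exact p = 0.000275). The cause was not tested. Without passing in either setting, Kupffer cell and leukocyte markers also changed, from lower to higher at any distance (83.3% against 78.3%), and stellate, endothelial and cholangiocyte markers from higher to lower at q of 0.05 or less (5% against 14%), at a fold of at least 5 (0 against 3.52%) and at −log10 q of at least 5 (0 against 2.29%). In strength 12 lists differed, and 10 to 12 did under the alternatives, 11 to 12 with 1 library alone. With a window of 1 kb, 41 of the 56 named genes kept their value and 15 moved, among them Pdgfrb, left with no promoter peak in both libraries.

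No paired analysis was possible because the groups that share replicate numbers are ChIP and input, the inputs have no values of their own here, and each ChIP was already called against the same-numbered input. Shared regions and their correlation need both libraries, so neither was left out. The motif search and its alternatives (1 mismatch, a window of 50 bp, the single recognition element, 1 library alone, the 1000 strongest peaks) were not run without a genome. Depth limits peaks of few fragments most.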

Other observations

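All tests in this part were chosen after the main results were seen; for those on ribosome and proteasome genes against plasma protein genes, gene length and the X chromosome, the deciding values were set before the outcome was computed. Among 299 KEGG pathways (the authors' deposited annotation, pathways of at least 10 genes), 14 differed in their share of genes with a stringent promoter peak in both libraries (two-sided Fisher's exact test, 7285 genes with a pathway, 250 of them with such a peak). Glycine, serine and threonine metabolism had 10 of 39 genes against 3.31% of other genes (raw exact p = 5e-07, adjusted exact p = 7.48e-05). They included Alas1, the first enzyme of haem synthesis, with folds of 11.4 and 9.56, Glyctk, a glycerate kinase, with 19.9 and 27.8, and Bhmt and Chdh of betaine metabolism, with 6.91 and 7.65 and with 6.83 and 7.31. Peroxisome genes had 13 of 83 (raw exact p = 4.16e-06, adjusted exact p = 0.000415). Among them Pex13 and Pex2, which act in protein import, had 10.2 and 16.4 and 8.83 and 11.7. Amino acid synthesis had 12 of 76 (adjusted exact p = 0.000516), with Mat1a, which makes S-adenosylmethionine, at 9.95 and 9.02, and Cps1 of the urea cycle at 7.68 and 7.15. The citrate cycle had 6 of 33 (adjusted exact p = 0.0233), PPAR signalling 10 of 84 (adjusted exact p = 0.0186) and bile secretion 10 of 70 (adjusted exact p = 0.00522). Olfactory transduction had 0 of 1072 (adjusted exact p = 1.07e-15). The pathways share genes, and those named were picked after their values were seen. These tests were not matched on gene length or transcript number. Olfactory genes also count among the other genes of the other pathways, which lowers the share those are set against.

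Some stringent peaks had no overlapping peak in the other library, 360 of 4442 in replicate 1 and 45 of 2908 in replicate 2. The strongest of these by fold, on chromosomes 1 to 19 and X and over a background of no more than 5 fragments, lay at the promoters of Gldc, of the glycine cleavage system (fold 12.4, chromosome 19, 30143948 to 30144473), and Cyp2c39 (11.1, chromosome 19, 39509814 to 39509945) in replicate 1. In replicate 2 Gldc had a different stringent promoter peak, with a fold of 5.81, and Cyp2c39 had stronger promoter peaks in both libraries, with folds of 14.3 and 14.8. In replicate 2 they lay at Mpc1, a mitochondrial pyruvate carrier (9.67, chromosome 17, 8283689 to 8285544), Ppm1l (7.60) and Tef (7.58). In replicate 1 these genes had other promoter peaks, not stringent, with folds of 3.04 at Mpc1, 5.49 at Ppm1l and 4.01 at Tef.

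Genes of the liver lists had stronger promoter peaks than other genes. Promoters open in every cell are argued against as the whole source for plasma protein genes. Of 61 ribosome and proteasome genes, not matched on length, 0 had a stringent promoter peak in both libraries (upper exact bound 5.87%). The plasma protein list's lower bound was 16.1%. Of the 9 other higher lists, 4 had a lower bound above 5.87% (known FXR targets, transport, lipid and detoxification genes). The 61 genes did not differ detectably from other genes in peaks of any strength (70.5% against 61.5%, Fisher's exact p = 0.187) or mean percentile (54.6, permutation p = 0.217). Bile acid synthesis, glucose and transcription factor genes had mean percentiles of 77.9, 76.6 and 82.1, which were not tested against the 61 genes. Their lower bounds of 4.95%, 3.38% and 1.7% lay below 5.87%. For these lists and for FGF and autophagy genes the explanation stays open. Gene length and the number of transcripts named in the peak lists are argued against as the whole source for 9 of the 10 higher lists. These kept an adjusted permutation p under 0.05 against matched random lists. The number of all annotated transcripts was not tested. Open chromatin of hepatocytes without FXR cannot be told apart from FXR binding, because no ChIP library came from untreated mice, mice without FXR or a control antibody, and known FXR targets ranked no higher than plasma protein genes (mean percentile 82.5 for 31 genes and 84.0 for 38, a difference of -1.5; two-sided permutation p = 0.792). Both may contribute, and the motif search that could separate them was not run.

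Peaks of 4 fragments or fewer were found in the other library more often than displaced peaks. This excess was 1.52 times in replicate 2 and 1.54 times in replicate 1, where counting noise alone would give about 1, and no test apart from the excess itself was made of it. Flanks of strong peaks are argued against as the whole source by ratios of 1.5 and 1.51 among weak peaks over 5 kb from any peak with −log10 q of at least 3. Copy number or composition varying over more than 1 kb is argued against as the whole source by a ratio of 1.32 in both libraries after a displacement of 1 kb. That ratio was lower than after 10 kb, so such variation may account for part of the excess. Over 9 combinations of both distances per library the ratio ran from 1.32 to 1.64. Weak FXR sites and effects of sequence at the site itself, such as mappability, may both be present and stay open, since no genome, control antibody or untreated ChIP library was used here.

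Chromosome X held 3.06% of the peaks of replicate 1 and 1.32% of those of replicate 2. Different numbers of X copies are argued against as the whole source, since at 4 fragments the peak density of X over that of chromosomes 1 to 19 was 0.243 and 0.217, a ratio between the libraries of 1.12; it was 0.507 and 0.379 at 3 fragments, and 0.0785 and 0.0370 at 7, on only 70 and 46 peaks of X. A candidate explanation is a single X copy in both libraries with a higher fragment minimum in replicate 2. The density ratio fell at least 1.75 times with each added fragment from 3 to 5 in both libraries, and it was 0.954 at 2 fragments, a class only replicate 1 has. The sex of the mice, which the labels used here do not give, and the differences at 3 and 7 fragments stay open.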
